A study of Homo sapiens with 10 samples.

How the data were processed

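RNA from HEK-293 cells, a human embryonic kidney line with some neuronal features, was measured on Affymetrix expression arrays after transfection of small interfering RNAs (siRNAs). Per the labels' protocols, biotinylated cRNA was made from total RNA taken 48 hours after transfection. The 10 arrays fell into 5 groups of 2: a control siRNA at 10 nM, 2 different siRNAs against the long non-coding RNA LOC440173 at 10 nM, the control siRNA at 100 nM, and an siRNA against PAXIP1-AS1 at 100 nM. The labels call the 2 arrays of each group biological replicates. The groups came from the labels alone.

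The deposited values were on the log2 scale, 1 column per array and 1 row for each of 32321 probe sets. The submitters' processing notes name RMA (background correction, quantile normalization and probe set summary) and limma, with no versions. The array definition file, the genome build and any filter are not given in the sources used here. Array medians lay between 7.06 and 7.12, and no further scaling was applied. Scanner intensities were not used here, so the level above background of each probe set is unknown. The number of arrays limits the precision.

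Gene names came from the platform annotation. It gave a single gene symbol for 19158 probe sets and several for 1388, while 11775 were not listed. Symbols were compared through gene IDs with a RefSeq gene table (assembly GRCh38.p14), which held 18375 of the IDs, lacked 29 and changed 0 symbols. Its coordinates were not used, only names and the order of neighbouring genes. LOC440173 is LINC02893 in that table and had 1 probe set. PAXIP1-AS1 is PAXIP1-DT there and had 0 listed probe sets, so its own level was not analysed here. For the 637 genes with several probe sets, the one with the highest mean over all arrays stood for the gene, which left 18404 genes. In the PAXIP1-AS1 comparison, 36 of these genes were called by their brightest probe set and 14 of them also by the mean of all their probe sets.

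All 10 arrays entered a single limma fit (version 3.58.1 in R 4.3.3) with a mean per group, followed by eBayes. The 5 groups shared an estimate of the spread with 5 residual and 2.87 prior degrees of freedom. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. A gene past this threshold is named called, higher or lower. With 2 arrays against 2, an exact permutation test cannot go below p = 0.333, so the calls rest on the pooled spread. The contrasts were each LOC440173 siRNA and their mean against the control at 10 nM, siRNA 2 against siRNA 1, the PAXIP1-AS1 siRNA against the control at 100 nM, both control doses, and the difference between the PAXIP1-AS1 effect and the mean LOC440173 effect. Errors of log2 fold changes are standard errors (SE) of this fit, and errors of group levels are standard deviations (SD) of 2 arrays.

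Before the data were examined, the design, the alternatives, the rule for named genes and 33 gene lists were fixed. The rule took, for each main contrast, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap on any array and whose higher group mean was at or above 7.65, the median of all genes. For the contrast of siRNA 2 with siRNA 1 and for the control doses it took 5 each way, by unadjusted p where no gene was called. It added the targets, the 3 annotated neighbours on each side, PAXIP1, and the 4 members with the smallest p of each called list. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists of each contrast, and again with the correlation estimated per list. Counts of list members are given over all genes and adjusted over the list alone.

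Both LOC440173 contrasts share their control arrays, so 100 datasets with unchanged groups were simulated from the fitted spread to give the agreement that shared controls alone produce. The code was tested on simulated data of 18404 genes with 200 changed genes in each of 10 datasets. For the PAXIP1-AS1 contrast it recovered 23.0% of genes changed by 1.25-fold, 81.3% by 1.5-fold and 98.8% by 2-fold, and 4.02% of all calls were false. For siRNA 1 and siRNA 2 it recovered 84.2% and 80.1% of genes changed by 1.5-fold, and 4.87% and 6.14% of calls were false, the last above the nominal 5%. The real contrasts of these siRNAs called 5301 and 5512 genes, far more than 200, so these rates may not hold for them. In 20 simulated datasets a list shifted by -0.2 was called in 20 and other lists in 0. Of 40 list calls in the real data 36 were lost with an estimated correlation, so these rates may not hold for them.

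The alternatives were another quantile normalization, the mean of all probe sets, every probe set on its own, genes below the median level left out, only the compared groups in the fit, an intensity trend with a robust prior, an added 1.5-fold minimum, the replicate number as a block, array weights, and each array left out in turn. The array weights came out equal for both arrays of each group, from 0.576 for the control at 10 nM to 1.50 for the PAXIP1-AS1 siRNA. They therefore weigh groups and do not check the quality of single arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.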

Results

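The series measured gene expression in HEK-293 cells in which 1 of 2 long intergenic non-coding RNAs had been silenced. LOC440173, now named LINC02893, was targeted by 2 siRNAs at 10 nM, and PAXIP1-AS1, a transcript that starts beside the gene for the chromatin adaptor PAXIP1, by 1 siRNA at 100 nM. Each experiment had a control siRNA at its own dose. All 5 groups held 2 arrays, with 32321 probe sets each and array medians of 7.06 to 7.12 (log2). Replicate arrays correlated at r = 0.997 to 0.998 across probe sets, which are not independent replicates. A pair of components carried most of the variance, 39.3% and 34.3%. The first placed siRNA 1 at -20.8 and -20.9 and siRNA 2 at 27.0 and 30.6, with the other arrays between -5.49 and -0.43. The second placed the arrays of both LOC440173 siRNAs between -23.1 and -10.6 and the other arrays between 9.02 and 16.7.

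LINC02893 itself was lower with both of its siRNAs. Its level was 8.54 ± 0.091 (log2, SD, n = 2) in the control at 10 nM, 7.58 ± 0.20 with siRNA 1 and 6.65 ± 0.086 with siRNA 2. The log2 fold change was -0.96 (SE 0.099, limma adjusted p = 0.000305) with siRNA 1, or 51.4% of the control, and -1.89 (SE 0.099, adjusted p = 1.38e-05) with siRNA 2, or 27.0% of the control. The direct contrast of siRNA 2 with siRNA 1 was -0.93 (adjusted p = 0.000177). With the PAXIP1-AS1 siRNA LINC02893 differed by -0.01 (95% interval -0.24 to 0.22, adjusted p = 0.976). The silencing of PAXIP1-AS1 was not analysed here, since no probe set was assigned to it. PAXIP1, its divergent neighbour and a subunit of a histone H3K4 methyltransferase complex, differed by 0.02 (95% interval -0.09 to 0.13, adjusted p = 0.919) with the PAXIP1-AS1 siRNA.

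**Figure D1:**
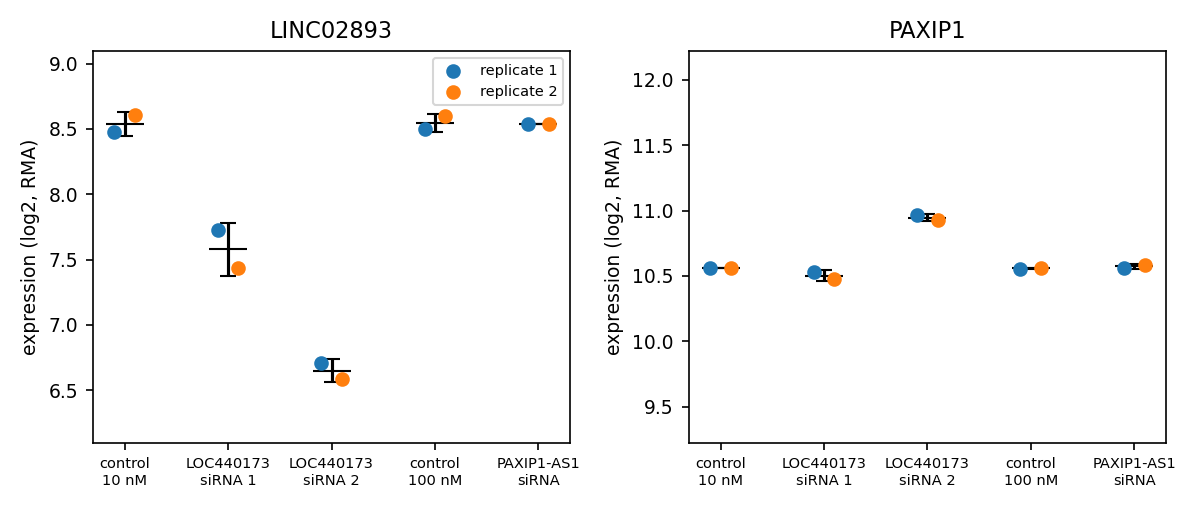
Expression (log2, RMA) of LINC02893 and PAXIP1 in the 5 groups; points are single arrays, horizontal lines group means and bars the SD of 2 arrays. LINC02893 was at 7.58 with siRNA 1 and 6.65 with siRNA 2 against 8.54 in their control, and PAXIP1 was at 10.57 with the PAXIP1-AS1 siRNA against 10.56 in its control.

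Genes beside the targets were also compared, because some long non-coding RNAs act on nearby genes. Next to LINC02893, GAS1, a growth arrest protein and hedgehog co-receptor, differed by 0.08 with siRNA 1 and -0.08 with siRNA 2 (adjusted p = 0.410 and 0.452), and the RNA uridylyltransferase TUT7 by 0.00 with both (0.977 and 0.986). ISCA1, an iron-sulfur cluster assembly factor, was lower with siRNA 1 (-0.51, SE 0.11, adjusted p = 0.0119) and higher with siRNA 2 (0.40, SE 0.11, 0.0294). The ISCA1 probe set is number 8112331, while those of LINC02893 and its other listed neighbours run from 8156196 to 8162187. The location of the ISCA1 probe set was not checked, so it is unknown whether these changes are those of the gene beside LINC02893. The kinase DAPK1 was lower with siRNA 1 (-0.21, adjusted p = 0.0452) and the pseudogene NFYCP2 higher (0.28, 0.0439), while with siRNA 2 they differed by -0.17 (0.0975) and 0.03 (0.853), DAPK1 being called with dim genes left out (0.0333) or a trend and robust prior (0.0424). Each siRNA 1 call was lost without any of the 8 arrays other than those of siRNA 2 (adjusted p from 0.0580 to 0.241 for DAPK1 and from 0.0592 to 0.180 for NFYCP2), and after another quantile normalization (0.0828 and 0.105). Both of these siRNA 1 calls were also lost with only the compared groups in the fit (adjusted p = 0.114 and 0.0603). DAPK1 was lost with array weights (0.0763) and NFYCP2 with a trend and robust prior (0.0831). LINC02872 differed by 0.38 with siRNA 1 (adjusted p = 0.0504) and 0.05 with siRNA 2 (0.824). The first was called without control 10 nM replicate 1 (0.0149) or either array of siRNA 2 (0.0369), with a trend and robust prior (0.0443) and with array weights (0.0483). The ISCA1 calls were lost without siRNA 1 replicate 1 (adjusted p = 0.0784) or control 10 nM replicate 2 (0.0688) for siRNA 1, and without siRNA 2 replicate 2 (0.157) or control 10 nM replicate 1 (0.142) for siRNA 2, where the call was also lost with only the compared groups in the fit (0.105). With array weights the ISCA1 call with siRNA 2 was lost as well (adjusted p = 0.0613). Around PAXIP1-AS1, none of ACTR3B, DPP6, PAXIP1, HTR5A, INSIG1 and EN2 was called with the PAXIP1-AS1 siRNA, with values from -0.23 for DPP6 to 0.07 for HTR5A (adjusted p = 0.320 and 0.907). DPP6 was dim, at 5.09 against 5.32 in its control, near the lower quartile of the arrays. ACTR3B, at -0.21 (adjusted p = 0.106), was called under 4 alternatives, with the smallest adjusted p of 0.0249 when dim genes were left out. The LOC440173 siRNAs moved some of them: PAXIP1 was higher with siRNA 2 (0.38, SE 0.048), INSIG1, a brake on sterol synthesis, was higher with siRNA 1 (0.40, SE 0.048), and the homeobox gene EN2 was lower with siRNA 1 (-0.88, SE 0.11) and higher with siRNA 2 (0.34, adjusted p = 0.0427). With array weights EN2 was not called with siRNA 2 (adjusted p = 0.154). The EN2 call with siRNA 2 was lost without any of the 8 arrays other than those of siRNA 1 (adjusted p from 0.0641 to 0.161).

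The comparison of LOC440173 siRNA 1 with its control asked which genes change with this siRNA. Cyclin D2 (CCND2), which drives entry into the cell cycle, was lower by a log2 fold change of -2.92 (SE 0.069, n = 2 per group), the actin-binding profilin PFN2 by -2.91 (SE 0.072) and the cystine transporter SLC7A11 by -2.38 (SE 0.078). Other large falls among called genes at or above the median level whose groups did not overlap were the zinc transporter SLC39A1 (-1.92), the matrix protein SPON1 (-1.85), ceramide kinase CERK (-1.79), podocalyxin PODXL, a surface sialomucin of podocytes (-1.79), the mitochondrial adenylate kinase AK4 (-1.78), the corepressor RUNX1T1 (-1.76) and PTGFRN (-1.74). Rises by the same rule were smaller, led by the interferon-inducible IFI35 (1.36, SE 0.066), FAXDC2 (1.35), the respiratory complex I subunit NDUFB5 (1.30), LRRC46 (1.27), the ubiquitin ligase adaptor KLHL24 (1.24), STARD3NL (1.22), carbonic anhydrase CA2 (1.21), the axonemal dynein DNAH6 (1.20), galectin LGALS1 (1.16) and SNAPC1 (1.12). Adjusted p for these 20 genes lay between 1.93e-06 and 0.00117. With siRNA 2, SLC7A11 (0.41), IFI35 (-0.37) and FAXDC2 (-0.55) were called the other way. PFN2 (0.16), SLC39A1 (-0.10), NDUFB5 (0.19), LRRC46 (0.20), DNAH6 (0.50) and LGALS1 (-0.11) were not called with siRNA 2, and the others were called the same way. In all, limma called 5301 of 18404 genes, 2229 higher and 3072 lower. At 2-fold or more 19 were higher and 194 lower. The count was 3494 with only the compared groups in the fit, 3294 without siRNA 1 replicate 1 and 3423 without siRNA 1 replicate 2.

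Among the 33 gene lists, 6 were called with siRNA 1. None was called with an estimated correlation. Of 29 mitotic genes 18 were higher and 0 lower (22 higher adjusted over the list alone; median 0.23, camera adjusted p = 1.14e-05, and 0.433 with an estimated correlation). CDC20, KIF2C, CCNB1 and CDC25C, which drive chromosome segregation and entry into mitosis, rose by 0.49, 0.54, 0.45 and 0.53. In the list of ATF4 targets and amino acid metabolism 18 of 30 were lower and 3 higher (20 and 3 adjusted over the list alone; median -0.27, 1.14e-05, and 0.267 with an estimated correlation), among them SLC7A11, the hormone STC2 (-1.03) and the amino acid transporters SLC7A5 (-0.98) and SLC7A1 (-0.80). Of 26 p53 targets 12 were lower and 1 higher (15 and 2 adjusted over the list alone; median -0.20, 0.00241, and 0.267), led by TP53INP1 (-1.38) and ZMAT3 (-0.95). Glycolysis and hypoxia genes were lower in 12 of 30 and higher in 5 (16 and 7 adjusted over the list alone; median -0.14, 0.0328, and 0.267), with hexokinase HK2 at -1.27. Matrix and TGF-beta genes were lower in 14 of 30 and higher in 4 (15 and 6 adjusted over the list alone; median -0.18, 0.0112, and 0.267), with lysyl oxidase LOX at -1.03 and fibronectin FN1 at -0.67. Immediate early and ERK genes were lower in 9 of 25 and higher in 0 (9 and 1 adjusted over the list alone; median -0.17, 0.0112, and 0.318), with JUN at -0.45 and DUSP1 at -0.47. The glycolysis call was also lost without siRNA 1 replicate 1 (adjusted p = 0.0509) and after another quantile normalization (0.122), and the immediate early call without control 10 nM replicate 1 (0.0868). With dim genes left out only the mitosis and ATF4 lists stayed called, and the adjusted p of the p53 list was 0.0953.

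Among called genes at or above the median level whose groups did not overlap, the largest fall with LOC440173 siRNA 2 was that of ATP6V0D1, a subunit of the proton pump that acidifies lysosomes, at -2.52 (SE 0.046, n = 2 per group). The membrane protein MYADM (-2.33, SE 0.047), the decoy TRAIL receptor TNFRSF10D (-2.27, SE 0.067), the mitochondrial cyclophilin PPIF (-2.26), RCAN3 (-2.24), ZCCHC12 (-2.24), ANAPC13, part of the anaphase-promoting complex (-2.22), SEPTIN3 (-2.15), C12orf57 (-1.95) and the endoplasmic reticulum retrieval receptor KDELR3 (-1.93) followed. The largest rises by the same rule were those of UNC13A, which primes synaptic vesicles (2.11, SE 0.10), the kinase HIPK3 (1.86, SE 0.060), the histone gene H2BC14 (1.49), PITHD1 (1.48), the arrestin-related ARRDC3 (1.48), the small GTPases RAB3C (1.47) and RAB39A (1.45), the laminin chain LAMC1 (1.44), MIF4GD (1.43) and the ephrin receptor EPHA7 (1.36). Adjusted p for these genes lay between 3.8e-07 and 0.000185. With siRNA 1, ARRDC3 (-1.24) and MYADM (0.39) were called the other way. UNC13A (0.15), H2BC14 (0.25), RAB3C (0.22), ATP6V0D1 (0.03), ANAPC13 (0.02) and KDELR3 (0.17) were not called with siRNA 1, and the others were called the same way. The fit called 5512 genes, 2307 higher and 3205 lower, of which 46 and 218 changed by 2-fold or more. The count was 2788 with only the compared groups in the fit.

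All 6 lists called with siRNA 2 were lower, and none was called with an estimated correlation. Genes of DNA replication and the G1/S step were lower in 21 of 35 and higher in 1 (21 and 2 adjusted over the list alone; median -0.26, camera adjusted p = 9.43e-05, and 0.287 with an estimated correlation), among them cyclin E1 CCNE1 (-1.40), the DNA methylation cofactor UHRF1 (-1.26) and the replicative helicase subunits GINS3 (-1.04) and GINS4 (-0.74). Of 26 p53 targets 15 were lower and 1 higher (17 and 2 adjusted over the list alone; median -0.27, 9.43e-05, and 0.126 with an estimated correlation), led by TP53INP1 (-1.09), SPATA18 (-0.93), TP53I3 (-0.91) and MDM2 (-0.84). Of 25 genes of autophagy and the lysosome 14 were lower and 4 higher (14 and 5 adjusted over the list alone; median -0.29, 0.00294, and 0.319), with ATP6V0D1, LAMP1, the neuraminidase NEU1 (-1.07) and the galactosidase GLA (-0.84). Matrix and TGF-beta genes were lower in 12 of 30 and higher in 2 (the same counts adjusted over the list alone; median -0.15, 0.00294, and 0.126): TIMP1 (-1.82), FN1 (-1.70) and ACTA2 (-1.47) fell while LAMC1 rose. Glycolysis and hypoxia genes were lower in 15 of 30 and higher in 4 (17 and 4 adjusted over the list alone; median -0.16, 0.00399, and 0.126), with PGK1 at -1.12. Wnt and Notch targets were lower in 10 of 20 and higher in 3 (11 and 3 adjusted over the list alone; median -0.26, 0.0330, and 0.393), with the stem cell receptor LGR5 at -1.58 and HEY1 at -0.94. The Wnt and Notch call was also lost without siRNA 2 replicate 1 (adjusted p = 0.0629) or control 10 nM replicate 1 (0.112), and after another quantile normalization (0.0512). With dim genes left out only the DNA replication and p53 lists stayed called.

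Interferon response genes, which double-stranded RNA can induce, were not called as a list with either siRNA. Their medians were 0.07 with siRNA 1 (4 higher and 3 lower of 38, adjusted p = 0.302) and -0.02 with siRNA 2 (0 higher and 9 lower, 0.452). Kidney tubule markers had medians of 0.11 and 0.01 (adjusted p = 0.285 and 0.520), and podocyte and nephron progenitor markers 0.08 and -0.05 (0.417 and 0.432). Lists of hepatocyte, fibroblast and endothelial, blood cell and keratinocyte markers had adjusted p of 0.121, 0.255, 0.223 and 0.224 with siRNA 1, and 0.718, 0.765, 0.718 and 0.897 with siRNA 2.

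Averaging both LOC440173 siRNAs gave 4754 called genes, 1721 higher and 3033 lower. Among called genes at or above the median level whose groups did not overlap, CCND2 (-2.36, SE 0.060), the metalloprotease inhibitor TIMP3 (-1.71, SE 0.11), ZCCHC12 (-1.65), RCAN3 (-1.64), SPON1 (-1.62), CERK (-1.61), the peroxidase PXDN (-1.54), PPIF (-1.46), the glutathione transferase MGST1 (-1.43) and LINC02893 (-1.43) fell the most. Rises by the same rule were led by MIF4GD (2.37-fold), EPHA7 (log2 1.16, SE 0.057), CA2 (1.15), HIPK3 (1.15), the mitochondrial dehydrogenase HSD17B10 (1.15), KLHL24 (1.03), PITHD1 (1.03), HINT2 (1.01), RAB39A (0.97) and CENPBD1P (0.96). Adjusted p of these 20 genes lay between 4.72e-06 and 0.000208. CCND2, TIMP3 and PXDN differed by 0.08, -0.01 and -0.08 with the PAXIP1-AS1 siRNA. Of the 33 lists, 7 were called for the mean and 0 with an estimated correlation. Mitotic genes were higher (15 of 29 higher and 2 lower, or 16 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.000623, and 0.726 with an estimated correlation). The other lists had lower medians: p53 targets (17 of 26 lower and 1 higher, also over the list alone; median -0.31, 4.39e-05), matrix and TGF-beta genes (17 of 30 lower and 2 higher, also over the list alone; -0.25, 0.000623) and glycolysis and hypoxia (14 of 30 lower and 3 higher, or 15 and 4 over the list alone; -0.17, 0.00144), each with an adjusted p of 0.0879 with an estimated correlation. Wnt and Notch targets (9 of 20 lower and 0 higher, also over the list alone; -0.15, 0.0214), ATF4 and amino acid genes (15 of 30 lower and 4 higher, or 16 and 6 over the list alone; -0.19, 0.0224) and autophagy and lysosome genes (11 of 25 lower and 3 higher, or 11 and 4 over the list alone; -0.08, 0.0248) had 0.482, 0.704 and 0.647 with an estimated correlation. The last 2 averages hide opposite medians: the ATF4 list had 13 higher and 6 lower with siRNA 2 (median 0.08, adjusted p = 0.244), and the autophagy list 6 higher and 5 lower with siRNA 1 (median 0.08, 0.594). With dim genes left out the glycolysis, Wnt and Notch, ATF4 and autophagy lists were not called for the mean (0.0685, 0.814, 0.400 and 0.386). The Wnt and Notch call was lost without control 10 nM replicate 1 (0.0805). The ATF4 and autophagy calls were lost without siRNA 2 replicate 1 (0.0588 for both) or control 10 nM replicate 2 (0.115 and 0.0535), and the autophagy call after another quantile normalization (0.127).

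The 2 LOC440173 siRNAs agreed for part of these genes. Of 2708 genes called with both, 584 were higher and 1142 lower with both, and 982 (36.3%) went opposite ways. Independent lists of the same sizes would give 279 and 535 in the same direction, and 388 higher with siRNA 1 and lower with siRNA 2, where 436 were seen, and 385 the other way, where 546 were seen. Simulated unchanged groups against the shared controls gave 0 such genes on average, and neither value alone measures a shared effect. Across genes, which are not independent, log2 fold changes correlated at r = 0.26 with a covariance of 0.0243, against a covariance of 0.00471 (and r of 0.50) in the simulation, a difference in covariance of 0.0196. Simulated arrays were independent, while replicate differences correlated at 0.53 between the control at 10 nM and siRNA 2. The controls were not split, since each part would hold 1 array, so part of the agreement may come from them. The same-direction count was 1726, and it was 791 with only the compared groups in the fit and 1130 without siRNA 1 replicate 1. Without control 10 nM replicate 1 the correlation was 0.38.

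**Figure D2:**
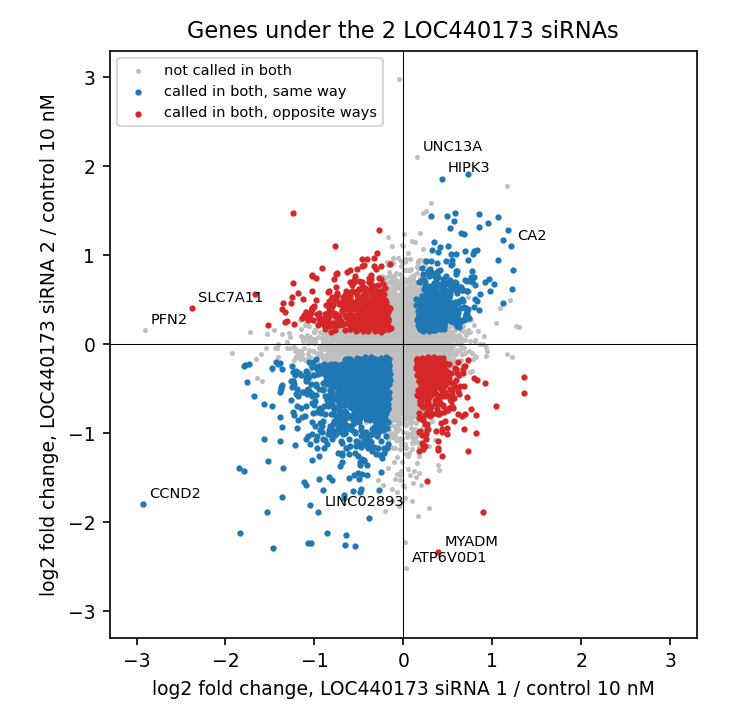
Log2 fold change of each of 18404 genes with LOC440173 siRNA 1 (x axis) and siRNA 2 (y axis) against the control at 10 nM; points are genes, in blue those called in both in the same direction and in red those called in opposite directions. The 1726 blue genes include CCND2, LINC02893 and CA2, and the 982 red genes include SLC7A11 and MYADM.

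Tested directly, siRNA 2 and siRNA 1 differed in 6836 genes, 3348 higher with siRNA 2 and 3488 lower. PFN2 was higher with siRNA 2 by 3.06 (SE 0.072), SLC7A11 by 2.79 (SE 0.078), ARRDC3 by 2.72, BTBD1 by 2.23 and UNC13A by 1.95. The neuropeptide gene CALCB (-2.79, SE 0.080), MYADM (-2.73), ATP6V0D1 (-2.55), ANAPC13 (-2.24) and the splicing-associated chaperone DNAJC8 (-2.13) were lower with siRNA 2. Adjusted p of these 10 genes lay between 1.75e-07 and 1.37e-05. ATF4 and amino acid genes were higher with siRNA 2 (19 of 30 higher and 3 lower, or 21 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 3.96e-06, and 0.502 with an estimated correlation), including CTH (1.78), STC2 (1.43) and ASNS (1.31). DNA replication genes were lower (23 of 35 lower and 4 higher, or 24 and 5 adjusted over the list alone; median -0.32, 0.000105, and 0.502 with an estimated correlation), including CCNE1 (-1.45), UHRF1 (-1.43), GINS3 (-1.14) and E2F1 (-0.83). Autophagy and lysosome genes were lower as well (14 of 25 lower and 3 higher, or 15 and 4 adjusted over the list alone; median -0.23, 0.00741, and 0.502 with an estimated correlation), including NEU1 (-1.31), LAMP1 (-1.26) and the cathepsin CTSB (-1.02).

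The PAXIP1-AS1 siRNA, compared with the control at 100 nM, changed fewer genes. Among called genes at or above the median level whose groups did not overlap, the integrin chain ITGA8, needed for kidney development, rose the most, by 1.60 (SE 0.12, n = 2 per group), followed by the late endosomal GTPase RAB9A (1.47, SE 0.065), CA2 (1.39, SE 0.048), TMEM9B (1.33), the mitochondrial serine hydroxymethyltransferase SHMT2 (1.32), STARD3NL (1.27), HIPK3 (1.23), NDUFB5 (1.19), the ubiquitin ligase RNF167 (1.15) and the metalloprotease ADAM9 (1.07). The largest falls by the same rule were those of smooth muscle actin ACTA2 (-1.85, SE 0.062), the light neurofilament chain NEFL (-1.13, SE 0.066), SPATA18 (-1.06, SE 0.065), TP53INP1 (-0.87), the death receptor FAS (-0.86), TNFRSF10D (-0.75), the cell cycle inhibitor CDKN1A (-0.75), RAP1B (-0.74), MORN2 (-0.74) and C4orf46 (-0.73). Adjusted p of these 20 genes lay between 2.79e-05 and 0.00772. RAB9A, CA2, TMEM9B, SHMT2 and STARD3NL also rose, and SPATA18 and TP53INP1 also fell, by at least 1.5-fold with both LOC440173 siRNAs. RAP1B has another probe set, dimmer, which differed by 0.21 (adjusted p = 0.744), and the mean of both was not called (-0.27, 0.362). The called probe set is number 8112728 and the dimmer one 7956937. Their locations were not checked, so it is unknown whether the fall is that of RAP1B itself. FAS lost its call without PAXIP1-AS1 replicate 1 (adjusted p = 0.0666) or control 100 nM replicate 2 (0.0563). MORN2 and RAP1B lost theirs without PAXIP1-AS1 replicate 1 (0.0759 and 0.0661), replicate 2 (0.0582 for both) or control 100 nM replicate 2 (0.0550 and 0.0557), and MORN2 with only the compared groups in the fit (0.0503).

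In all, 850 of 18404 genes were called with the PAXIP1-AS1 siRNA, 526 higher and 324 lower. At 1.5-fold or more 83 were higher and 29 lower, and at 2-fold or more 16 and 4. The count depended on the spread estimate and on single arrays. It was 181 with only the compared groups in the fit, 432 with every probe set tested, 1879 with dim genes left out and 1784 with a trend and robust prior. With array weights, which were equal within each group, it was 1544. The replicate number as a block raised the count by over 1.5 times, as given further below. It was 135 and 187 without control 100 nM replicates 1 and 2, 117 and 110 without PAXIP1-AS1 replicates 1 and 2, and 477 without either replicate of LOC440173 siRNA 1.

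Targets of the tumour suppressor p53 had a lower median with the PAXIP1-AS1 siRNA. Of 26 measured members 13 were lower and 0 higher (21 lower adjusted over the list alone; median -0.39, camera adjusted p = 3.95e-20, and adjusted p = 0.0104 with an estimated correlation). SPATA18, TP53INP1, CDKN1A and the quinone reductase TP53I3 (-0.72, SE 0.067) led the list. The list of NRF2 targets and metallothioneins was higher, with 7 of 20 members higher and 0 lower (10 higher adjusted over the list alone; median 0.25, adjusted p = 2.3e-08, and 0.0197 with an estimated correlation). Its leading members were SLC7A11 (0.83, SE 0.078), the metallothioneins MT1F (0.59) and MT1X (0.46) and malic enzyme ME1 (0.55). Glycolysis and hypoxia genes were higher in 4 of 30 and lower in 1 (10 and 1 adjusted over the list alone; median 0.11, adjusted p = 2.18e-05, and 0.0356 with an estimated correlation). ENO2 (0.57), BNIP3 (0.35) and EGLN3 (0.31) rose and NDRG1 (-0.29) fell.

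**Figure D3:**
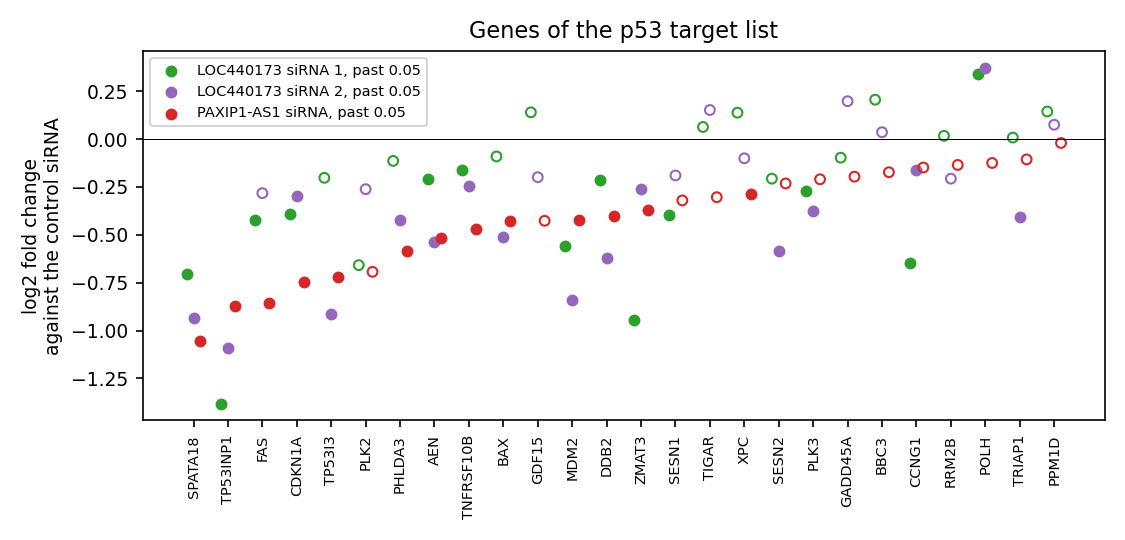
Log2 fold change of the 26 measured genes of the p53 target list with each target siRNA against the control siRNA at its dose; filled points had an adjusted p below 0.05 and open points did not. With the PAXIP1-AS1 siRNA 13 were lower and 0 higher; with LOC440173 siRNA 1 and siRNA 2, 12 and 15 were lower and 1 was higher.

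For the other 7 lists called with the PAXIP1-AS1 siRNA, all higher, the call was lost with an estimated correlation. The ATF4 and amino acid list had 9 of 30 members higher and 0 lower (14 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 6.61e-07, 0.215 with an estimated correlation), led by SHMT2, the serine synthesis enzyme PHGDH (0.93, SE 0.051) and the stress protein DDIT4 (0.99, SE 0.075). Of 29 mitotic genes only CDC20 (0.51, SE 0.051) was called, with 8 higher adjusted over the list alone (median 0.14, 2.84e-06, and 0.561 with an estimated correlation). Of 19 cholesterol synthesis genes only ACAT2 (1.02, SE 0.075) was called (3 over the list alone; median 0.12, 0.00771, and 0.441 with an estimated correlation). ACAT2 also rose with LOC440173 siRNA 1 and siRNA 2 (0.78 and 1.02), as did SHMT2 (0.78 and 0.71). In the list of RNA interference machinery TNRC6B (0.49), TNRC6A (0.33) and AGO2 (0.29), which act in silencing by small RNAs, were higher and TNRC6C (-0.28) lower of 14 (5 and 2 adjusted over the list alone; median 0.11, 0.0121, and 0.239 with an estimated correlation). Histone genes had 1 of 18 higher, H3-3B (0.30; 3 adjusted over the list alone; median 0.10, 0.0172, and 0.721 with an estimated correlation), and fatty acid genes 1 of 20, FADS2 (0.33; 4 adjusted over the list alone; median 0.06, 0.0427, and 0.384 with an estimated correlation). DNA damage response genes had 0 of 21 called (0 adjusted over the list alone; median 0.05, 0.0427, and 0.847 with an estimated correlation). Without control 100 nM replicate 1 the cholesterol, RNA interference, histone, fatty acid and DNA damage lists were not called (adjusted p = 0.0805, 0.0592, 0.295, 0.178 and 0.577). Without PAXIP1-AS1 replicate 2 the same held for the RNA interference, histone, fatty acid and DNA damage lists (0.0566, 0.0566, 0.136 and 0.422). After another quantile normalization the fatty acid and DNA damage lists were not called (0.0575 and 0.101), nor was the fatty acid list with the replicate block (0.0673). With dim genes left out the RNA interference, histone, fatty acid and DNA damage lists were not called (0.0587, 0.0587, 0.149 and 0.173).

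PAXIP1 and its KMT2C/KMT2D complex had 0 of 10 members called with the PAXIP1-AS1 siRNA (median 0.01, adjusted p = 0.928). Interferon response genes had a median of 0.00 (1 of 38 higher, adjusted p = 0.978), and kidney tubule markers -0.04 (1 of 23 higher, 0.928). Markers of hepatocytes, of fibroblasts and endothelium, of blood cells and of keratinocytes had medians of -0.03, 0.02, 0.02 and -0.05 (adjusted p = 0.853, 0.853, 0.912 and 0.548).

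Control siRNA at 100 nM and at 10 nM gave no called gene. With limma 0 of 18404 genes passed, 692 had an unadjusted p below 0.05, and the smallest adjusted p was 1.00. The genes with the smallest unadjusted p were DGCR6 (0.33), the glutathione transferase GSTA3, MST1 (0.65), FRG2C and TCHH (0.43) upward, and CCDC62 (-0.41), LOC100287290 (-0.35), ABCB5, LOC100131943 (-0.43) and RGS9BP (-0.47) downward. GSTA3 (4.48 at 100 nM against 3.89 at 10 nM), FRG2C (4.24 against 3.98) and ABCB5 (3.67 against 3.98) lay below the lower quartile of every array, so only their levels are given. Glycolysis and hypoxia was the only list called, with 0 of 30 members called (0 adjusted over the list alone; median -0.05, camera adjusted p = 0.00602, and 0.267 with an estimated correlation). That call was lost without control 10 nM replicate 2 (0.273) or control 100 nM replicate 1 (0.106). Dose and experiment go together in these groups and were not separated.

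The effect of the PAXIP1-AS1 siRNA differed from the mean effect of the LOC440173 siRNAs in 2129 genes, 1617 with a higher and 512 with a lower value for PAXIP1-AS1. SLC7A11 differed by 1.82 (SE 0.10), the matrix genes FN1 and TIMP1 by 1.12 and 0.98 and the endoplasmic reticulum chaperone HYOU1 by 0.96, while ACTA2 differed by -0.84 and the neurofilament NEFM by -0.69. Several of these rest on a single LOC440173 siRNA. SLC7A11 was at -2.38 with siRNA 1, 0.41 with siRNA 2 and 0.83 with the PAXIP1-AS1 siRNA, TIMP1 at -0.05, -1.82 and 0.04, HYOU1 at -0.01, -1.58 and 0.17, and NEFM at -0.77, 1.11 and -0.52. Of 7 called lists, glycolysis and hypoxia was also called with an estimated correlation (13 of 30 higher and 0 lower, or 21 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 6.5e-09, and 0.0282 with an estimated correlation). SLC2A1 (0.79), HK2 (0.77), PFKFB3 (0.73) and PGK1 (0.69) led it. ATF4 and amino acid genes (15 of 30 higher and 1 lower, or 21 and 1 adjusted over the list alone; median 0.31, 1.18e-09), NRF2 and metallothionein genes (7 of 20 higher, or 10; 0.22, 6.34e-05), the unfolded protein response (5 of 23, or 8; 0.21, 0.00124), DNA replication (11 of 35, or 13 and 1 lower; 0.12, 0.00838) and matrix and TGF-beta genes (9 of 30 higher and 2 lower, with the same counts over the list alone; 0.14, 0.0221) were higher. Neuronal markers were lower (3 of 21, also over the list alone; -0.20, 0.0143), and that call was lost without control 10 nM replicate 2 (0.0603). With an estimated correlation these 6 lists had adjusted p of 0.136, 0.0708, 0.314, 0.360, 0.195 and 0.436. With dim genes left out, the DNA replication, unfolded protein response, matrix and neuronal lists were not called (0.204, 0.0695, 0.153 and 0.161). The ATF4 list had medians of -0.27 with siRNA 1, 0.08 with siRNA 2 and 0.14 with the PAXIP1-AS1 siRNA. The DNA replication list had 0.10 (13 higher and 7 lower), -0.26 and -0.00, so its difference came with the fall under siRNA 2. The p53 list was not called in this contrast (median -0.15, adjusted p = 0.0521). The count of genes was 1033 and 1193 without control 100 nM replicates 1 and 2, and 1067 and 923 without PAXIP1-AS1 replicates 1 and 2.

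Some genes moved the same way with all 3 target siRNAs, a comparison chosen after the data were seen. It held 144 genes called higher and 103 called lower in each of the 3 comparisons. Simulated unchanged groups gave 0 on average, but with no changed gene they do not measure how far real responses are shared. If the genes called the same way with both LOC440173 siRNAs, which share controls, were independent of the PAXIP1-AS1 calls, 16.7 and 20.1 would be shared. At 1.5-fold or more in each, 19 were higher and 7 lower. The 19 included CA2 (1.21, 1.10 and 1.39 with siRNA 1, siRNA 2 and the PAXIP1-AS1 siRNA), RAB9A (0.80, 1.05 and 1.47), HSD17B10 (1.12, 1.18 and 1.01), HINT2 (1.06, 0.95 and 1.01), the endosomal sorting ATPase VPS4A (0.78, 0.82 and 0.96) and the translocon subunit SEC61B (0.77, 0.72 and 0.93). TMEM9B, SHMT2, STARD3NL and ACAT2 were also among them. The 7 were CCNC, AHNAK2, GPR50, OSTN and 3 genes that p53 is known to activate, TP53INP1 (-1.38, -1.09 and -0.87), SPATA18 (-0.71, -0.93 and -1.06) and EDA2R (-0.92, -0.98 and -1.10). All 3 comparisons set a target siRNA against the same control siRNA, though on different arrays for PAXIP1-AS1. The count of 247 was 135 and 138 without LOC440173 siRNA 1 replicates 1 and 2, 57 and 79 without control 100 nM replicates 1 and 2, and 56 and 51 without PAXIP1-AS1 replicates 1 and 2. It was 129 with every probe set tested, 507 with dim genes left out and 473 with a trend and robust prior.

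**Figure D4:**
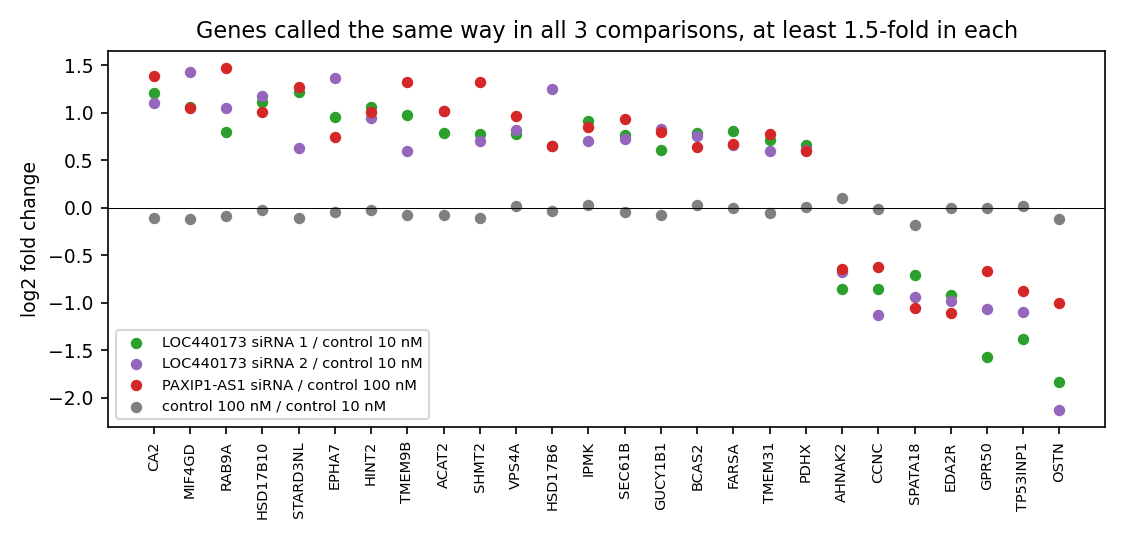
Log2 fold changes of the 26 genes called the same way in all 3 comparisons and changed at least 1.5-fold in each; coloured points show each target siRNA against its control and grey points the control at 100 nM against the control at 10 nM. The 19 higher genes run from CA2 to PDHX and the 7 lower ones from AHNAK2 to OSTN, and 0 of the 18404 genes were called between the control doses.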

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

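The tests of LINC02893 in the PAXIP1-AS1 group, of array scale, of other transcripts as targets, of separate processing of the siRNA 1 arrays and of p53 genes with the LOC440173 siRNAs were chosen after the results were seen, as was the set of genes shared by all 3 comparisons.

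Several results differ between the 2 LOC440173 siRNAs. LINC02893 was lower with siRNA 2 than with siRNA 1 by a log2 difference of -0.93, 6836 genes differed, and 982 were called in opposite ways against the control. Of the genes annotated near LINC02893, ISCA1 was higher with siRNA 2 by 0.91, on a probe set whose location was not checked and may lie elsewhere. Near PAXIP1-AS1, PAXIP1 was higher by 0.44, EN2 by 1.22, and INSIG1 differed by -0.54. Lists that differed were DNA replication and G1/S (median -0.32), ATF4 and amino acid metabolism (0.42) and autophagy and lysosome (-0.23). The last 3 were not called with an estimated correlation (adjusted p = 0.502).

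For the genes that differ between the LOC440173 siRNAs, a dose effect of LINC02893 loss predicts few genes that go opposite ways, while 36.3% of the genes called with both did, which argues against it as the whole explanation. Array scale moves genes of the same level alike. A curve over gene level explained 0.445% of the variance of the difference among these genes, so little difference of scale was left. The deposited values were already quantile normalized, which takes out most of such a curve. The low value therefore cannot decide on array effects that normalization leaves behind. The labels give no processing batch, and separate processing of the siRNA 1 arrays is argued against only as the whole explanation, since 32.4% of the differing genes were called with siRNA 2 and not with siRNA 1. For the 28.7% called with siRNA 1 and not with siRNA 2 it cannot be told apart from an effect of that siRNA. The same holds for the 1725 differing genes called with both siRNAs and the 931 called with neither. Their differences also use the siRNA 1 arrays, as do the calls in opposite ways set against a dose effect. Silencing of other transcripts by each siRNA also stays open and cannot be told apart from a shared effect by the share of falls among 2-fold changes. With siRNA 1 this share was 92.8% of 194 genes that differ and 73.7% of 19 that do not (19.1 percentage points, Fisher p = 0.0171). With siRNA 2 it was 82.7% of 243 and 81.0% of 21 (1.76 percentage points, Fisher p = 0.769). So few genes that do not differ could hardly decide.

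The response differed between the PAXIP1-AS1 and LOC440173 experiments in 2129 genes. The lists that differed had medians of 0.12 (DNA replication and G1/S), 0.21 (unfolded protein response), 0.31 (ATF4 and amino acid metabolism), 0.27 (glycolysis and hypoxia), 0.14 (matrix and TGF-beta), -0.20 (neuronal markers) and 0.22 (NRF2 and metallothioneins). With an estimated correlation 1 of these 7, glycolysis and hypoxia, was called. Without control 10 nM replicate 2 the neuronal list was not called (adjusted p = 0.0603).

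For the genes that moved the same way with all 3 target siRNAs, an effect of the control siRNA on its own groups is a candidate explanation. Genes silenced in both control groups would appear as rises in every comparison. Rises made up 73.1% of the 26 genes changed 1.5-fold or more, and 58.3% of all 247 genes, shares that decide neither way. With both LOC440173 siRNAs 43 genes were called higher and 167 lower at 1.5-fold or more. Of these, 24 rises and 15 falls were also called the same way with the PAXIP1-AS1 siRNA, which called 526 rises and 324 falls. Rises were thus shared more often than falls, which goes with an effect of the control siRNA without deciding for it. Such an effect cannot be told apart from an effect common to the target siRNAs, because there was no untransfected group and no other control siRNA. Loss of LINC02893 is argued against in the PAXIP1-AS1 group, where LINC02893 differed by -0.010. Loss of either RNA acting on the same genes stays open and was not tested.

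For the lower p53 targets with the PAXIP1-AS1 siRNA, a single array is argued against: without any 1 of the 4 arrays the highest median of the list was -0.35 and its largest adjusted p was 5.77e-16. The list was lower with both LOC440173 siRNAs too, where the higher of the medians was -0.20, so the possibility that the control siRNA raised p53 targets in both control groups may explain part of it and remains open. Those LOC440173 calls were lost with an estimated correlation (adjusted p = 0.267 and 0.126). The difference between the experiments missed the threshold (median -0.15, adjusted p = 0.0521). Loss of PAXIP1-AS1 also remains open, and its level was not analysed here.

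Probe sets without a single gene name lie outside the report's comparisons of genes. Of 13163 such probe sets, 1015 were called with LOC440173 siRNA 1, 1010 with siRNA 2 and 62 with the PAXIP1-AS1 siRNA, against 0 between the control doses.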

How the results depend on the processing

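All alternatives were chosen before the data were examined, except those for the genes shared by all 3 comparisons and for the gene families. Over 80 recomputed gene counts, 60 stayed within 1.5 times of the reported count. Some of the 60 could not move. A 1.5-fold minimum cannot change the 0 calls between the control doses, and the difference between the experiments already uses all 5 groups. The counts that moved follow, and the cause was not tested unless stated. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, siRNA 1 gave 3494 calls, siRNA 2 2788, the same-direction count was 791 and PAXIP1-AS1 gave 181. The added 1.5-fold minimum removes smaller changes by construction. It left 1044 calls for siRNA 1, 1220 for siRNA 2, 601 for their mean, 1944 between the siRNAs, 112 for PAXIP1-AS1, 624 between the experiments, 210 in the same direction and 26 in all 3 comparisons. PAXIP1-AS1 gave 432 calls with every probe set tested, 1879 with dim genes left out, 1784 with a trend and robust prior and 1544 with array weights, against 850. The count for all 3 comparisons was 129, 507 and 473 under the first 3 of these, against 247. With dim genes left out the correlation of both LOC440173 siRNAs was 0.17, against 0.26.

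The labels do not say what a replicate number marks. Replicate differences correlated between groups at 0.07 to 0.09 for pairs with siRNA 1 and at 0.29 to 0.53 for the other pairs. The latter values point to a source of variation shared by number in the other 4 groups, though genes are not independent. The main fit has no term for it. With the replicate block PAXIP1-AS1 gave 1325 calls, and the other counts stayed within 1.5 times of those reported (6739 for siRNA 1 and 6328 for siRNA 2). With the block the fatty acid list was not called with the PAXIP1-AS1 siRNA (adjusted p = 0.0673), and LINC02872 was called with siRNA 1 (0.0367). Another quantile normalization moved the median of all genes by at most 0.03 and no split of higher and lower calls by over 10 percentage points.

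Leaving out each array in turn, with the lone array of a group assumed to vary like the others, gave 3294 to 5663 calls for siRNA 1, 4190 to 5155 for siRNA 2, 3547 to 4417 for their mean, 5229 to 7152 between them, 110 to 895 for PAXIP1-AS1, 0 to 0 for the control doses and 923 to 2139 between the experiments. It gave 1130 to 1678 in the same direction, 51 to 234 in all 3 comparisons and a correlation of 0.19 to 0.38. LINC02893 ranged from -1.10 to -0.82 with siRNA 1, -1.95 to -1.83 with siRNA 2, -1.07 to -0.79 between them and -0.060 to 0.040 with the PAXIP1-AS1 siRNA. Called lists numbered 5 to 9, 5 to 7 and 5 to 11 for siRNA 1, siRNA 2 and PAXIP1-AS1.

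With an estimated correlation 0, 0 and 3 lists were called, and with dim genes left out 2 with siRNA 1, 2 with siRNA 2 and 7 with the PAXIP1-AS1 siRNA, 6 of the last among the 10 reported. Of 40 list calls over all contrasts, 36 were lost with the estimated correlation, 21 with dim genes left out, 5 after quantile normalization and 1 with the block, and 21 of 400 without 1 array. Of 1350 values of named genes and neighbours without 1 array, 36 lost and 4 gained a call. Called lists and the named genes and neighbours called in the report kept their direction under the alternatives run on single genes. Neighbours that were not called changed direction 22 times without 1 array and 4 times after another quantile normalization. After the latter, NFYCP2 with siRNA 2 was at -0.012, DPP6 with siRNA 2 at -0.031, PAXIP1 with the PAXIP1-AS1 siRNA at -0.00064 and LINC02872 with it at 0.0076. Without 1 array, TUT7 ranged from -0.070 to 0.077 and HTR5A from -0.13 to 0.38 with siRNA 1. With siRNA 2 the ranges were -0.070 to 0.076 for TUT7, -0.097 to 0.16 for NFYCP2, -0.11 to 0.21 for LINC02872, -0.065 to 0.069 for ACTR3B, -0.13 to 0.15 for DPP6 and -0.15 to 0.36 for HTR5A. With the PAXIP1-AS1 siRNA they were -0.014 to 0.14 for TUT7, -0.023 to 0.019 for LINC02872, -0.043 to 0.18 for HTR5A and -0.030 to 0.023 for EN2. Signal over background was not measured here, so the limit it sets for dim probe sets is unknown.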

Other observations

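The gene families described next were grouped by symbol stem after the data were seen, with 118 stems of at least 15 genes tested in 3 comparisons. Intraflagellar transport genes, which build and maintain cilia, were higher with LOC440173 siRNA 1: 8 of 18 were higher and 0 lower (median 0.25, camera adjusted p = 0.0220, and 0.956 with an estimated correlation). IFT81 (0.68), IFT46 (0.53), IFT56 (0.47) and IFT172 (0.39) had the smallest p. With siRNA 2 the family was not called, and IFT46 and IFT81 were also higher (0.34 and 0.27) while IFT56 was lower (-0.21). With the PAXIP1-AS1 siRNA IFT46 was lower (-0.31, adjusted p = 0.0195). After another quantile normalization 10 of the 18 were higher and 0 lower with siRNA 1.

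Zinc finger genes of the ZNF stem, mostly DNA-binding repressors, were lower with LOC440173 siRNA 1. Of 483 genes 177 were lower and 18 higher (median -0.17, adjusted p = 4.22e-07, and 0.922 with an estimated correlation), and 183 and 19 after another quantile normalization. ZNF704 (-1.65), ZNF100 (-1.05), ZNF362 (-0.86) and ZNF121 (-0.85) had the smallest p. With siRNA 2 the ZNF family was not called, while ZNF100 was lower (-0.55) and ZNF121 higher (0.27). With the PAXIP1-AS1 siRNA the same genes had a median of -0.06, with 8 lower and 2 higher (adjusted p = 0.0264, and 0.996 with an estimated correlation). Many of these genes have near-identical relatives, so probes can be shared between them.

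Among probe sets without a single gene name, 62 were called with the PAXIP1-AS1 siRNA. Probe set 7896369 was at 9.87 against 11.28 in the control (log2 fold change -1.41, SE 0.10, limma adjusted p = 0.00313) and probe set 8135587 at 8.18 against 7.44 (0.73, SE 0.12, 0.0448). The other 2 of the 4 with the largest changes lay near the lowest values of the arrays in at least 1 group, so no fold is given: probe set 7942379 was at 3.87 against 2.95 and probe set 7991665 at 3.50 against 5.58, with lower quartiles of 5.28 to 5.40 over the arrays.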
